A study of Arabidopsis thaliana with 8 samples.

How the data were processed

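RNA of whole dark-grown seedlings was labelled with biotin and hybridised to ATH1 arrays, per the labels' protocols, with 1 array per sample, 8 arrays in 4 groups and 2 biological replicates per group. The deposited table gives 1 linear intensity per probe set and array, and per the submitters' processing notes MAS5 was used, with no role or version. How the authors scaled the deposited intensities is not given in the sources used here. The lowest value of each array lay between 2.48 and 2.69 and the lowest correlation within a group was 0.983 over the tested probe sets, which is unusual for plain MAS5 signals, so the summary method is left open and no background level can be stated. Arrays were already on a common scale, with upper quartiles between 101.5 and 104.7.

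The table held 22810 probe sets, of which 64 control probe sets were left out of the tests. Intensities were taken to log2(intensity + 16), which understates fold changes of dim genes, and the upper 60% of probe sets by mean over all arrays were kept, leaving 13648. limma 3.58.1 in R 4.3.3 fitted 4 group means to all arrays (lmFit, contrasts.fit, eBayes with a trend), with 4 residual and 6.28 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The 5 comparisons were zinc in each genotype, dez on each medium, and their interaction. The numbers 1 and 2 of the replicates are not stated to pair samples, so no block was fitted. On simulated data with the same spread, all 67 genes changed by 1 log2 unit and 46.3% of those changed by 0.5 were recovered for zinc in wild type (13648 genes). For the interaction, 89.6% and 13.4% were. False calls were 15 of 179 for zinc in wild type, 19 of 184 for dez on control medium and 7 of 142 for the interaction. The simulated noise was independent between genes and had the same spread in all groups.

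Genes were named through the probe annotation supplied with the array platform, updated to the symbols of the RefSeq annotation of TAIR10.1 by gene identifier. Of the probe sets outside the controls, 13513 had 1 gene, 503 had several and 8730 were not listed, and these last 2 kinds were not named; 13436 of the first kind matched RefSeq, and 53.4% of the tested probe sets were named. No coordinates were used. Before the data were examined 28 gene lists, the tests and the naming rule were fixed. Of 512 list genes, 94 had a probe set that names them and 70 were tested, so many well-known genes of these pathways are not reported here. 6 entries whose symbol belongs to another locus in RefSeq were left out. Lists were tested with camera (preset correlation 0.01, the brightest probe set per gene, lists of at least 5 tested genes: 4 lists, 20 tests adjusted together), beside camera with an estimated correlation and fry. The named genes were, per comparison, the 10 largest rises and falls past the threshold from probe sets of 1 gene with both arrays of one group beyond both of the other (not required for the interaction), up to 4 genes per list with the smallest adjusted p, and TBR.

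After seeing the data, further lists were formed: the antenna, photosystem and Calvin cycle lists joined (9 tested genes), plastid-encoded genes (63), class III peroxidases (34), suberin (5) and aliphatic glucosinolate synthesis (4). The suberin, peroxidase and glucosinolate lists were written because such genes stood among the largest changes, so they are no independent evidence of direction. Gene families sharing a symbol stem were tested in the same way. 2 alternatives were also added then. One scaled each array to the mean log2 intensity of the 3' probe sets of the poly-A spike controls (dap, lys, phe and thr). These controls are usually added per amount of total RNA, but the sources used here do not state that they were, or in equal amounts. Their mean log2 intensity was 7.43 and 7.91 on the 2 arrays of wild type on control medium and 6.94 and 6.61 on those of dez on high zinc. The other added the mean 3' minus 5' log2 difference of the actin and GAPDH controls, a sign of RNA quality and labelling, as a covariate. The alternatives chosen beforehand were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter at the upper 40%, eBayes without a trend or with a robust prior, a replicate block, each array left out in turn, only the 4 arrays compared, and 2 other thresholds.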

Results

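Transcript levels were measured in whole dark-grown seedlings of *Arabidopsis thaliana*, 7 days old, on Affymetrix ATH1 arrays, which read 1 sample per array with short probes grouped into probe sets. Wild-type seedlings and seedlings of the mutant dez were grown on control medium with 1 µM zinc or on high-zinc medium with 100 µM zinc. Each of the 4 groups had 2 biological replicates of about 45 seedlings, so 8 arrays were compared and their number limits the precision. The array medians of the deposited intensity lay between 34.7 and 37.2. The dez mutation is known to lie in TRICHOME BIREFRINGENCE (TBR, AT5G06700), a gene of the family that acetylates wall polysaccharides. TBR had a mean intensity of 161.0 ± 10.5 (SD, n = 2) in wild type on control medium, 136.6 ± 11.9 in wild type on high zinc, 121.9 ± 13.4 in dez on control medium and 144.2 ± 8.49 in dez on high zinc. It passed the test in no comparison, with limma adjusted p between 0.0864 and 0.661, and since the lesion is not given in the sources used here, its probe set does not check the genotype labels. Principal component 1 held 72.1% of the variance and set dez on high zinc, at 48.3 and 52.0, apart from the other 6 arrays, which lay between -25.5 and -5.29.

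**Figure D1:**
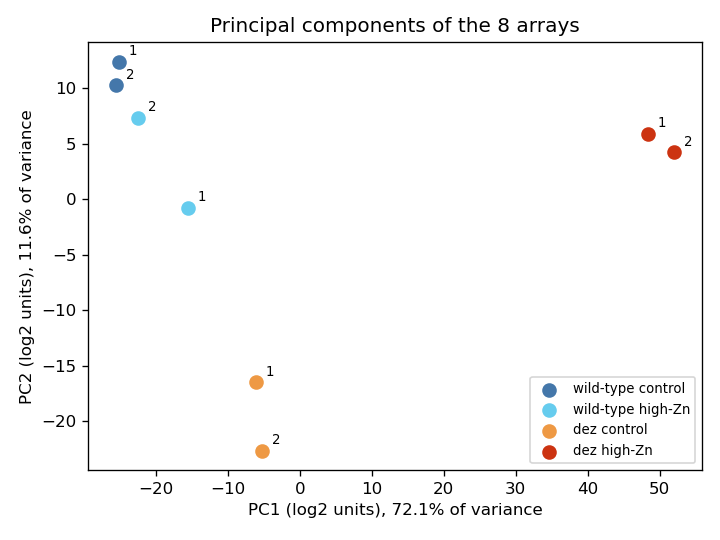
Each point is 1 array, placed by principal components 1 (72.1% of the variance) and 2 (11.6%) of the log2 intensities, coloured by group and marked with its replicate number. The 2 arrays of dez on high zinc lie at 48.3 and 52.0 on component 1, and replicate 1 of wild type on high zinc lies at -15.6 against -22.6 for replicate 2.

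The response of wild-type seedlings to high zinc was small, and the genes named here are those of probe sets that match 1 gene. AT3G58550 rose by 2.65 ± 0.13 on the log2 scale (SE, limma adjusted p = 1.81e-05), from a mean intensity of 26.4 ± 1.62 to 250.3 ± 10.3 (SD, n = 2). AT2G18370, a lipid transfer protein, rose by 2.22 ± 0.15 (adjusted p = 1.13e-04). FACT, an enzyme that makes alkyl caffeates of root waxes, rose by 1.86 ± 0.16 (adjusted p = 7.45e-04), from 18.0 ± 3.09 to 107.3 ± 11.4. The other 7 of the 10 largest rises lay between 1.06 and 1.69 on the log2 scale and included AT4G36430, a class III peroxidase, AT2G23540, AT5G37690, AT1G74460 and AT4G38080. AT4G37220 showed the largest fall, -1.79 ± 0.18 (adjusted p = 0.00127), followed by AT2G43535 with -1.23, OCT1, an organic cation transporter, with -1.17, and XTH19, a xyloglucan endotransglucosylase/hydrolase, with -1.14. SWEET11, a sucrose transporter, and TBL41, a relative of TBR, were also lower, by log2 values of -0.66 and -0.67. Of 9 tested genes of expansins and xyloglucan enzymes 1 rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone. The 9 tested chlorophyll and tetrapyrrole genes had a median of 0.33 and the 5 tested iron deficiency genes one of 0.23, and none passed the test alone; adjusted over the list alone, 4 and 1 of them rose. Both lists stood above the other genes by camera, with adjusted p = 0.00149 and 0.0137, but with an estimated correlation the adjusted p = 0.106 and the adjusted p = 0.22, and the iron list had camera adjusted p = 0.0858 without wild-type control replicate 2. The 9 photosynthesis genes (antenna, photosystem and Calvin cycle lists) lay between 0.11 and 0.51 and none passed, while 2 rose when adjusted over the list alone (camera adjusted p = 9.92e-05 for the 3 lists joined; adjusted p = 0.197 with an estimated correlation). With the 3'-5' difference of the actin and GAPDH controls as a covariate, the antenna and photosystem medians were 0.07 and 0.16, against 0.23 and 0.35 as deposited. The Calvin cycle median was 0.25 in both fits. That difference was 1.59 on high zinc and 1.78 on control medium in wild type. Of the 12 tested TBR family genes TBL41 alone passed, also when adjusted over the list alone. None of them passed with that covariate or under poly-A spike scaling. The 2 tested zinc deficiency genes and the 2 tested metal sequestration genes had medians of -0.01 and 0.11 with none past the threshold. Nor did any of the 4 auxin response genes pass, of which 3 were lower when adjusted over the list alone. In all, 96 of 13648 probe sets passed the threshold, 63 higher and 33 lower, and 37 of them changed at least 2-fold. Without wild-type control replicate 1 the split was 55 higher and 51 lower, with 60 of the 96 shared, and without either dez control array it was 53 and 21. The count was 49 without wild-type control replicate 2, 63 without wild-type high-Zn replicate 2, 54 without either dez high-Zn array and 26 with only the 4 wild-type arrays in the fit. Log2 differences between replicates had an SD of 0.230 and 0.237 in the wild-type groups and 0.156 and 0.193 in the dez groups. The fit of all arrays pools this spread, so it may understate that of wild type and 96 may be too many. Scaled to the spiked poly-A controls, an alternative chosen after seeing the data, 17 passed and 76.5% of them were higher, against 65.6% as deposited.

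High zinc had a far wider effect in dez. AT2G43620, a chitinase family gene, rose from 124.2 ± 2.87 to 2218 ± 387.6 (SD, n = 2), by 3.98 ± 0.14 on the log2 scale (SE, limma adjusted p = 5.83e-08). AT4G33720, a gene of the PR-1-like family, rose by 3.96 ± 0.11, and the lipid transfer protein-like genes AT4G12500 and AT4G12490 by 3.90 ± 0.11 and 3.84 ± 0.19. PRX52, a class III peroxidase, rose by 3.32 ± 0.22 and AT4G01700, another chitinase family gene, by 3.16 ± 0.10. ATPMEPCRD, a pectin methylesterase, showed the largest fall, from 489.9 ± 67.7 to 37.5 ± 1.39, a log2 change of -3.24 ± 0.12 (adjusted p = 1.04e-07). AT1G09750, AT5G44440 and AT5G48490 had log2 changes of -3.11, -3.02 and -2.73, and IAA29, an auxin response gene, one of -2.14 ± 0.13. All 9 tested photosynthesis genes fell, by log2 values from -1.61 for PSAN, a photosystem I subunit, to -0.42 for PSBY of photosystem II. They included LHCB4.2 (-1.16), PRK (-1.22), PSBW (-0.93) and RCA (-0.50); camera gave adjusted p = 2.51e-06 for the 3 lists joined, and adjusted p = 0.177 with an estimated correlation. Of the 9 chlorophyll and tetrapyrrole genes 6 fell, 1 rose and 2 did not pass (7 fell and 1 rose when adjusted over the list alone). Among them were CHLM (-1.30), PORB, a protochlorophyllide oxidoreductase (-1.30, limma adjusted p = 8.23e-05), CHLP (-1.06) and HEME2 (-0.87). HEMA2, a glutamyl-tRNA reductase, rose by 0.56, a call lost both with the 3'-5' covariate and under poly-A spike scaling. The list stood below the other genes by camera (adjusted p = 0.00169), a call lost at adjusted p = 0.106 with an estimated correlation. All 5 tested iron deficiency genes rose, also when adjusted over the list alone: S8H, a coumarin hydroxylase, by 2.38 ± 0.14, the peptide gene IMA1 by 1.46 ± 0.18, and F6'H1, BGLU42 and the regulator PYE by values from 0.84 to 1.04. Camera gave adjusted p = 2.23e-04 for this list, and adjusted p = 0.106 with an estimated correlation. Of the 9 expansin and xyloglucan genes 4 rose and 2 fell (5 and 3 when adjusted over the list alone), with XTH18 at 1.23 and EXPA8 at -1.61. Of the 12 TBR family genes 1 rose, TBL39 at 0.86, and 4 fell, with TBL45 at -1.30 (equal counts when adjusted over the list alone), and their median turned from -0.04 to 0.37 under poly-A spike scaling. In shorter lists, WRKY53, the 1 tested defence gene, rose by 1.95 ± 0.12, and both tested oxidative stress genes rose, ZAT10 by 1.52 ± 0.11 and GSTU25 by 1.36 ± 0.16. Of the 4 tested genes of pectin and wall sensing the pectin methylesterase PME41 rose by 2.195 ± 0.13 and SBT1.7 by 0.88, while the receptor kinase THE1 had a change of -0.42 ± 0.12, and counts in these lists were equal when adjusted over the list alone. HAT2 of the auxin response and ZIP6, 1 of the 2 zinc deficiency genes, had changes of -0.30 and -0.33, which turned to 0.11 and 0.08 under poly-A spike scaling. OLEO3, the 1 tested seed storage gene, had a change of -1.13 ± 0.22 (adjusted p = 0.00257), and BGLU23, the 1 tested root gene, one of -0.28 ± 0.10 (adjusted p = 0.0499), which turned to 0.13 under poly-A spike scaling. Beside these groups, the 25S ribosomal RNA control lay at 8.18 ± 0.48 (log2, SD, n = 2) in dez on control medium and 9.63 ± 1.195 on high zinc, and the 3'-5' difference of the actin and GAPDH controls at 1.46 ± 0.15 and 1.202 ± 0.015. In all, 4645 probe sets passed, 2271 higher and 2374 lower, and the count was 2964 and 2868 without dez control replicate 1 or 2. Scaled to the poly-A spikes the median of all probe sets moved to 0.42, 1156 passed and 91.5% of those were higher, against 48.9% as deposited; all 5 iron deficiency genes still rose, while 1 of the 9 photosynthesis genes and none of the chlorophyll genes still fell. Their medians in that scaling were 1.45, -0.52 and -0.46, against 1.04, -0.93 and -0.87 as deposited.

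**Figure D2:**
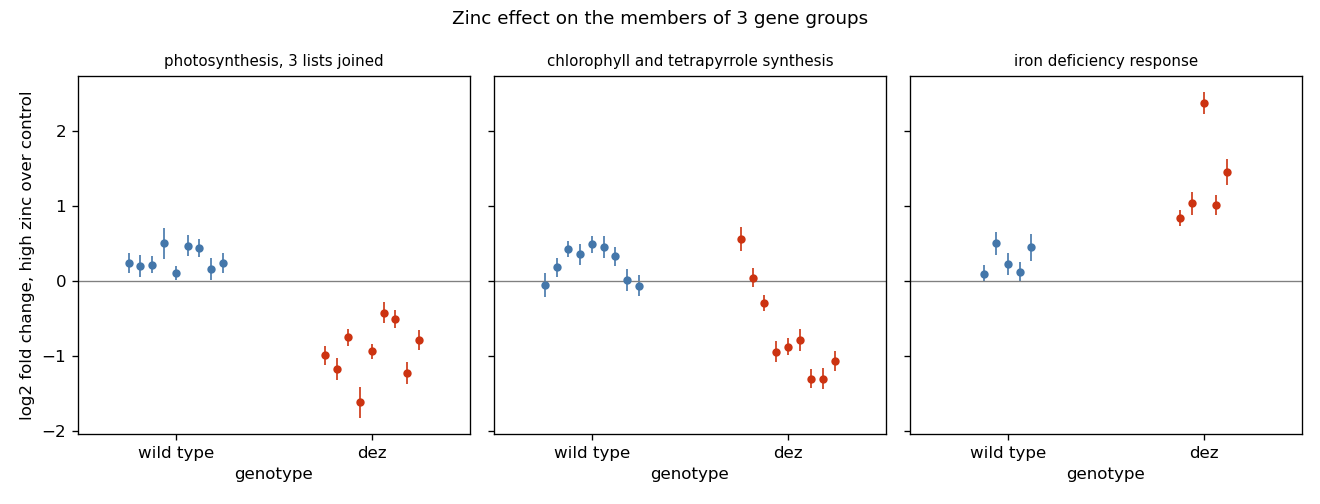
Each point is the log2 fold change of 1 gene, high zinc over control medium, with its standard error, in wild type (blue) and dez (red); the panels hold the 9 photosynthesis, 9 chlorophyll and tetrapyrrole and 5 iron deficiency genes. In dez the photosynthesis genes lie between -1.61 and -0.42 and the iron deficiency genes between 0.84 and 2.38, as deposited; scaled to the poly-A spikes, the photosynthesis median in dez was -0.52.

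On control medium dez already differed from wild type. BCAT4, an enzyme at the entry to methionine-derived glucosinolates, rose from 10.4 ± 2.71 to 131.3 ± 15.2 (SD, n = 2), by 2.48 ± 0.12 on the log2 scale (SE, limma adjusted p = 4.06e-06). AT3G45160 rose by 1.76 ± 0.16 and AT1G26380 by 1.60 ± 0.17, and AT2G23540 and AT5G37690, both also higher in wild type on high zinc, by 1.37 and 1.35. AT4G37220 had the largest fall, from 254.8 ± 82.7 to 9.66 ± 2.71, a log2 change of -3.37 ± 0.18 (adjusted p = 6.17e-06). AT1G19530 changed by -2.98 ± 0.26, GAT1_2.1, a glutamine amidotransferase-like gene, by -2.47 ± 0.16 and OCT1 by -1.97 ± 0.11. IVD and MCCA, both of leucine breakdown, changed by -1.76 ± 0.18 and -1.39 ± 0.23. Of the 5 iron deficiency genes F6'H1 rose by 1.23 ± 0.15 and IMA1 by 1.04 ± 0.18, and 3 rose when adjusted over the list alone; camera gave adjusted p = 0.0137, adjusted p = 0.22 with an estimated correlation and 0.0577 without wild-type control replicate 2. None of the 9 photosynthesis genes and none of the 9 chlorophyll genes passed, also when adjusted over the list alone. Of the 4 auxin response genes GH3.5 and HAT2 had changes of -0.65 and -0.64, and the median of the list turned from -0.34 to 0.14 under poly-A spike scaling. XTH19 had a change of -0.76, EXPB3 one of 0.55 and TBL41 one of -0.80. The 25S ribosomal RNA control probe set, a sign of ribosomal RNA in the labelled material, was higher in dez by 2.199 on the log2 scale. In all, 1308 probe sets passed, 573 higher and 735 lower. The count was 693 without wild-type control replicate 2, 519 without dez control replicate 1 and 359 without dez control replicate 2. Added after seeing the data, the 3'-5' difference of the actin and GAPDH controls as a covariate left 700, and poly-A spike scaling, which moved the median of all probe sets to 0.51, left 177, of which 83.6% were higher against 43.8% as deposited.

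On high zinc dez differed from wild type in many transcripts. AT2G43620 was higher in dez by 4.72 ± 0.14 on the log2 scale (SE, limma adjusted p = 1.64e-08), BCAT4 by 4.69 ± 0.12 (29.5 ± 0.59 against 1156 ± 13.0; SD, n = 2) and AT4G12490 by 4.63 ± 0.19. ATPMEPCRD, AT2G05540 and AT1G19530 were lower, with log2 differences of -4.01, -4.00 and -3.90, and the plastid gene petL had one of -2.74 ± 0.36. All 9 photosynthesis genes were lower, between -2.01 for PSAN and -0.83 for SBPASE, and 7 of the 9 chlorophyll genes were lower and 1 higher. Chlorophyll genes had camera adjusted p = 0.00149, and adjusted p = 0.106 with an estimated correlation. All 5 iron deficiency genes were higher, between 0.80 and 2.13 (camera adjusted p = 2.37e-04; adjusted p = 0.106 with an estimated correlation). These counts were equal when adjusted over the list alone. WRKY53 was higher by 2.11 ± 0.12, PME41 by 2.52 ± 0.13 and XTH18 by 1.43 ± 0.11, while EXPA8 differed by -2.11 ± 0.24 and IAA29 by -1.58 ± 0.13. Beside these groups, the 25S ribosomal RNA control lay at 9.63 ± 1.195 (log2, SD, n = 2) in dez on high zinc against 6.56 ± 0.07 in wild type on high zinc, and the 3'-5' difference of the actin and GAPDH controls at 1.202 ± 0.015 against 1.59 ± 0.11. In all, 5846 probe sets passed, 3026 higher and 2820 lower, and 3445 passed with that 3'-5' difference as a covariate. Scaled to the poly-A spikes the median of all probe sets moved to 0.84, 7732 passed and 98.2% of those were higher, against 51.8% as deposited, so directions here are relative to the other transcripts. In that scaling 2 of the 9 photosynthesis genes were lower, 2 of the 9 chlorophyll genes were lower and 2 higher, and all 5 iron deficiency genes were higher, with medians of -0.30, -0.23 and 2.57 against -1.11, -1.04 and 1.76 as deposited.

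**Figure D3:**
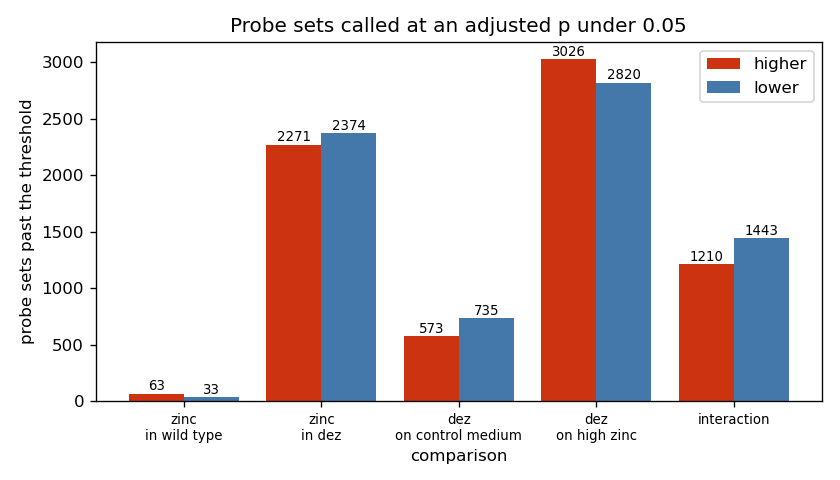
Bars give the number of the 13648 tested probe sets past an adjusted p of 0.05 in each comparison, higher (red) and lower (blue), from an axis that starts at 0, for intensities as deposited. The counts run from 63 higher and 33 lower for zinc in wild type to 3026 higher and 2820 lower for dez on high zinc; scaled to the poly-A spikes, 98.2% of the latter comparison's calls were higher.

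The interaction asks whether the effect of zinc differed between the genotypes. AT4G33720 and AT4G12500 had the largest positive interactions, 4.101 ± 0.16 and 3.79 ± 0.16 on the log2 scale (SE, limma adjusted p = 1.36e-06 and 1.41e-06). AT5G48490 and AT1G09750 had the largest negative ones, -3.59 ± 0.38 and -3.38 ± 0.17. All 9 photosynthesis genes had a negative interaction past the threshold, between -2.12 and -0.90, as had 7 of the 9 chlorophyll genes, with 1 positive and 7 negative when adjusted over the list alone (camera adjusted p = 2.23e-04; adjusted p = 0.106 with an estimated correlation). Of the 5 iron deficiency genes 4 had a positive one, and 5 when adjusted over the list alone (camera adjusted p = 8.60e-04; adjusted p = 0.121 with an estimated correlation). XTH18 and XTH19 had interactions of 1.77 and 1.72: XTH19 had a change of -1.14 with zinc in wild type and a mean intensity of 268.8 ± 12.2 on control medium and 408.4 ± 15.7 on high zinc in dez (SD, n = 2). In all, 2653 probe sets passed, 1210 positive and 1443 negative, and 1621 without dez control replicate 2. Without dez control replicate 1, 778 were positive. Scaled to the poly-A spikes the median of all probe sets moved to 0.35 and 244 passed, 87.7% of them positive against 45.6% as deposited, and 1 photosynthesis gene, 1 iron deficiency gene and none of the chlorophyll genes passed, with medians of -0.72, 1.22 and -0.91 against -1.05, 0.89 and -1.24 as deposited. Across the 13648 probe sets, which are not independent replicates, the zinc effects of wild type and dez had a Pearson r of 0.13 and a Spearman rho of 0.11, and r was 0.05 without wild-type high-Zn replicate 1. The effects of dez on control medium and on high zinc had r = 0.46 and rho = 0.41. For zinc, 65 probe sets were called in both genotypes, and 37 of them changed in the same direction. For dez, 945 were called on both media, and 846 of them did. Independent lists of these sizes would share 16.2 and 278.9 in the same direction. The rest of the 65 changed in opposite directions, for which no such value was computed. The excess over 16.2 thus does not show that the zinc effects agreed in direction.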

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

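The root marker test, poly-A spike scaling and the 3'-5' covariate were chosen after the results were seen, and the spike levels were known before the bounds for the scaling test were set.

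The effect of zinc differed between dez and wild type for 2653 probe sets by limma's interaction test. Median interactions on the log2 scale were -1.24 for chlorophyll and tetrapyrrole synthesis, 0.89 for the iron deficiency response, -1.05 for the 9 photosynthesis genes, -0.55 for 63 plastid-encoded genes and -1.43 for 5 suberin genes. These lists passed camera with the preset correlation and none did with an estimated one, at adjusted p = 0.106, 0.121, 0.172, 0.172 and 0.1 with an estimated correlation in that order, and the suberin list was written after its leading genes were seen. Under poly-A spike scaling the plastid-encoded median was -0.22 and 1 of the 63 genes passed, against 18 as deposited. The largest positive interactions were 4.101 for AT4G33720, 3.79 for AT4G12500, 3.68 for AT5G55050, 3.65 for AT4G22470, 3.36 for PRX52, 3.35 for AT2G43620, 3.31 for AT4G12490, 3.02 for AT1G43910, 2.93 for AT4G01700 and 2.86 for AT1G65500. The largest negative ones were -3.59 for AT5G48490, -3.38 for AT1G09750, -3.03 for AT5G44440, -2.76 for ATPMEPCRD, -2.40 for AT2G23540, -2.39 for AT3G47070, -2.36 for AT3G05600, -2.30 for AT4G18970, -2.24 for AT4G28780 and -2.23 for petL.

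Photosynthesis genes with a differing zinc effect were PSAN (-2.12), PRK (-1.38), LHCB4.2 (-1.37), LHCB4.1 (-1.23), PSBW (-1.05), SBPASE (-1.03), PSAE1 (-0.97), RCA (-0.95) and PSBY (-0.90). Chlorophyll genes among those that passed were CHLM (-1.63), HEME2 (-1.37), PORB (-1.31) and HEME1 (-1.30), and the 4 iron deficiency genes that passed were S8H (2.14), IMA1 (1.01), BGLU42 (0.89) and PYE (0.73). Wall genes among those that passed were XTH18 (1.77), XTH19 (1.72), PME41 (1.97), EXPB1 (-1.26), EXPB3 (-0.84), TBL45 (-1.49), TBL36 (-1.18), TBL39 (0.77) and TBL25 (-0.74). Stress and hormone genes among those that passed were WRKY53 (1.99), ZAT10 (1.45), GSTU25 (1.07), IAA29 (-1.68), EXO (0.78) and GID1B (0.61).

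Control probe sets, which were not tested themselves and enter only the poly-A spike scaling and the 3'-5' covariate, also differed from wild type on control medium. The 25S ribosomal RNA probe set was higher by 2.199 on the log2 scale in dez on control medium and by 3.66 in dez on high zinc. In dez on high zinc the 5' probe sets of GAPDH were higher by 1.12 and 1.02, and a further Arabidopsis control probe set by 1.39. Both GAPDH probe sets are part of the 3'-5' difference used as a covariate.

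With the 3'-5' difference as a covariate, the lower photosynthesis transcripts of dez on high zinc had a median for zinc in dez of -1.01. In that fit 8 of the 9 genes passed. This does not decide on labelling or RNA quality, because the slope of the covariate comes only from differences between replicates. The 2 replicates had 1.99 and 1.575 in wild type on control medium but 1.21 and 1.19 in dez on high zinc. The 25S ribosomal RNA control, at 8.18 in dez on control medium and 9.63 on high zinc, was not in the model. The median of the photosynthesis genes was -0.95 under both quantile normalization and median centring, and all 9 genes fell in each. Scaling to the poly-A spikes cannot be told apart: it moved every probe set by 0.41 and so the median from -0.93 to -0.52 (median absolute deviation 0.34 in both), with a median SE of 0.135 before and 0.36 after it, and 1 of the 9 genes passed. A smaller share of cotyledons against roots stays open too, since the 1 tested root gene, at -0.28, decides nothing. A lower share of photosynthesis transcripts in dez under high zinc may be biological, as a hypothesis that these arrays leave open.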

How the results depend on the processing

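The poly-A spike scaling and the 3'-5' covariate were chosen after the data were seen, and the other alternatives were planned. Intensities were already on a common scale, no background level is known, and 2 arrays per group limit the precision.

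Under poly-A spike scaling 17 probe sets passed for zinc in wild type, 1156 for zinc in dez, 177 for dez on control medium and 244 for the interaction; for dez on high zinc 7732 did, against 5846. Among named genes past the threshold as deposited or after this scaling, it turned the sign of HAT2 (0.11), BGLU23 (0.13) and ZIP6 (0.08) for zinc in dez, of GI (0.024) for dez on control medium, and of GH3.5 (0.22), HAT2 (0.30), GH3.3 (0.81), UGT78D2 (0.41), cemA (0.20), COB (0.81) and ZIP6 (0.34) for dez on high zinc. With the 3'-5' covariate 700 passed for dez on control medium and 3445 for dez on high zinc, and the correlations across genes were 0.24 for zinc effects and 0.53 for dez effects. Of the named genes' values 118 kept their direction but were no longer past the threshold under spike scaling, and 23 with the covariate. Spike scaling subtracts 1 value per array, and this value differed between replicates, as in wild type on high zinc (7.305 and 7.864). For the 9 photosynthesis genes the median SE for zinc in dez was 0.135 as deposited and 0.36 after spike scaling. Calls lost in that scaling therefore need not mean smaller effects. Beyond this the cause was not tested.

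With at least a 2-fold change also required, 37, 805, 209, 1162 and 941 passed for zinc in wild type, zinc in dez, dez on control medium, dez on high zinc and the interaction. At an adjusted p under 0.1, 194 passed for zinc in wild type and 2119 for dez on control medium. With only the 4 arrays compared, 26 passed for zinc in wild type but 5586, against 4645, for zinc in dez. The correlation of dez effects was 0.48 with the upper 40% filter. Quantile normalization, median centring, both pseudocounts, no filter and both other eBayes settings kept every count within 1.5 times and turned no named gene that passed the test before or after the change.

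All 9 camera calls of the fixed lists were lost with an estimated correlation, at adjusted p = 0.106 for chlorophyll and tetrapyrrole synthesis (zinc in wild type, zinc in dez, dez on high zinc, interaction), and for iron deficiency 0.22 (zinc in wild type, dez on control medium), 0.106 (zinc in dez, dez on high zinc) and 0.121 (interaction). By fry the iron list for zinc in wild type had 0.0897. A robust prior was not run for camera, which has no such option, and with the upper 40% filter some lists fell under 5 genes and some named genes were not tested.

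Leaving out 1 array at a time assumes that the lone array of a group varies like the others. Counts ranged from 49 (without wild-type control replicate 2) to 106 for zinc in wild type, from 2868 (without dez control replicate 2) to 4853 for zinc in dez, from 359 (without dez control replicate 2) to 1517 for dez on control medium, from 4225 to 6029 for dez on high zinc and from 1621 (without dez control replicate 2) to 2791 for the interaction. Other counts that moved by over 1.5 times were 63 without wild-type high-Zn replicate 2 and 54 without either dez high-Zn array for zinc in wild type, 2964 without dez control replicate 1 for zinc in dez, and 693 and 519 without wild-type control replicate 2 or dez control replicate 1 for dez on control medium. Correlations ranged from 0.051 (without wild-type high-Zn replicate 1) to 0.20 (without wild-type high-Zn replicate 2) for zinc effects and from 0.41 to 0.47 for dez effects. The iron list ranged from adjusted p = 0.00792 to 0.0858 for zinc in wild type and from 0.00296 to 0.0577 for dez on control medium, both highest without wild-type control replicate 2.

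With a replicate block 116, 4371, 1133, 5564 and 2464 passed for the 5 comparisons. Deviations of same-numbered replicates correlated between -0.363 and 0.375 across pairs of groups, so the numbers were not taken to pair samples.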

Other observations

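The lists described first were chosen after the leading genes were seen, as were poly-A spike scaling, the 3'-5' covariate and the symbol families.

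Suberin genes, which build a lipid barrier in root cell walls, rose with zinc in wild type in 5 of 5 tested members, with a median of 1.35 on the log2 scale (camera adjusted p = 1.47e-13; adjusted p = 0.0598 with an estimated correlation). Several of them had been seen among the largest rises, so the list is not independent evidence of its direction. With zinc in dez FACT rose by 0.47, AT1G74460, AT2G23540 and AT2G48130 had changes of -0.86, -0.97 and -0.53, and all 5 interactions passed (median -1.43; camera adjusted p = 2.22e-06; adjusted p = 0.1 with an estimated correlation). On control medium 3 of the 5 were higher in dez, and on high zinc 4 of the 5 were lower (median -1.06, and -0.24 with none past the threshold under poly-A spike scaling). Under poly-A spike scaling 2 rose with zinc in wild type, none passed with zinc in dez and 2 interactions passed, with medians of 1.43, -0.12 and -1.10 against 1.35, -0.53 and -1.43 as deposited. With the 3'-5' covariate 3 rose with zinc in wild type (median 1.296), none rose and 3 fell with zinc in dez, and all 5 interactions passed. In wild type that 3'-5' difference was 1.59 ± 0.11 (log2, SD, n = 2) on high zinc and 1.78 ± 0.295 on control medium, and the 25S ribosomal RNA control lay at 6.56 ± 0.07 and 5.98 ± 0.69.

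All 4 tested genes of aliphatic glucosinolate synthesis rose with zinc in dez (median 1.34) and were higher in dez on control medium (1.27) and on high zinc (2.26), and their interactions passed (1.01). Under poly-A spike scaling 4, 3, 4 and 1 of them passed, with medians of 1.75, 1.76, 3.08 and 1.34. Of 34 class III peroxidases 19 rose and 4 fell with zinc in dez, and 13 rose and none fell under that scaling (median 0.46 as deposited and 0.87 after it). For this list camera gave adjusted p = 0.00161, and adjusted p = 0.118 with an estimated correlation. With zinc in wild type 4 of the 34 rose and 0 fell (median 0.13; camera adjusted p = 1.94e-04; adjusted p = 0.1 with an estimated correlation). The interaction of the list did not pass (median 0.33; camera adjusted p = 0.103). No difference between the genotypes was thus shown for the list as a whole. Of 63 plastid-encoded genes 26 fell with zinc in dez (median -0.47, and -0.06 with 1 lower under poly-A spike scaling), and 32 were lower and 2 higher in dez on high zinc, where that scaling turned the median from -0.45 to 0.36. With the 3'-5' covariate 14 fell with zinc in dez (median -0.35), and 7 were lower and 0 higher in dez on high zinc (median -0.30); that 3'-5' difference was 1.46 in dez on control medium, 1.59 in wild type on high zinc and 1.202 in dez on high zinc. Camera gave adjusted p = 5.24e-07 for the former, and adjusted p = 0.177 with an estimated correlation. Of 140 tests of 28 symbol families 14 passed with the preset correlation and 0 with an estimated one.

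Across 13648 probe sets, which are not independent replicates, the effect of dez on control medium had a Pearson r of 0.59 with the effect of zinc in wild type. Both comparisons use the wild-type control arrays: 100 simulated draws with no effect gave a mean r of 0.50 and a mean covariance of 0.009, against 0.040 observed. With a different control array for each comparison r was 0.41 and 0.26, which argues against independent noise of the shared arrays as the whole cause. A deviation common to both control arrays would stay in both comparisons, and this test cannot exclude it. The 25S ribosomal RNA control was 5.98 in wild type on control medium, 6.56 in wild type on high zinc and 8.18 in dez on control medium. The 3'-5' difference of the actin and GAPDH controls was 1.78, 1.59 and 1.46 in that order. Wild-type high-Zn replicate 1 alone cannot be told apart, since without it r was 0.317 and 0.088. Without replicate 2 instead, r was 0.406 and 0.430, so the resemblance was stronger with replicate 1. These values rest on single wild-type arrays and on the mean of the 2 dez control arrays. Wild-type high-Zn replicate 1 correlated with dez control replicate 1 at 0.9836 and with its own replicate at 0.9831. That dez on control medium resembles wild type on high zinc is a hypothesis found on these arrays, which leave it open.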
